A study of Mus musculus with 8 samples.

How the data were processed

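Bulk RNA sequencing measured polyA RNA of gamma delta (γδ) T cells sorted from the visceral adipose tissue of C57BL/6 mice. Per the labels, 4 samples came from mice on control chow and 4 from mice on a ketogenic diet (KD), a diet low in carbohydrate and high in fat that raises circulating ketone bodies, and feeding lasted 1 week. The labels number the samples 1 to 4 within each diet. They do not say whether a sample is a single mouse or a pool, so p-values here measure the spread between these samples, which may in part be technical. RNA was extracted in RLT buffer and libraries followed standard Illumina procedures, per the labels' protocols. The strand setting of the libraries is not given in the sources used here. Single-cell data that the series' design text mentions were not analysed here.

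The authors deposited a table of estimated counts per gene, made with tools that the submitters' processing notes name, and a table of FPKM values (fragments per kilobase of gene) for the same samples. Those notes list BWA, TopHat2, RSEM and DESeq2 and the mouse build GRCm38, without versions or roles. Between 5310 and 5802 genes per sample had an estimated count that was not whole. Estimated counts divide reads shared by similar genes, so levels of near-identical copies are less certain than those of unique genes. The counts were rounded to whole numbers before any count test. Every value column was mapped to a sample by its title. A spreadsheet had turned 27 gene symbols into dates, and all 27 were restored through their Ensembl identifiers. No pair of samples held identical counts.

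The tables list 47729 genes, of which 22672 had a count in at least 1 sample. Library totals ran from 19796112 to 31926427 counts, and a floor of 3 counts corresponded to 0.0947 to 0.152 CPM (counts scaled to a common library total) in single libraries. Intervals of count ratios are exact binomial (95%). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Genes were kept by edgeR's filterByExpr rule (minimum count 10, minimum total 15), which left 13397. Libraries were scaled with TMM factors, and CPM values use TMM-scaled library sizes. KD was compared with chow by edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, robust, two-sided, diet as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are KD minus chow, with a standard error (SE) taken from the fold change and its F statistic. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Data were simulated from these samples' means and library sizes (13397 genes, 200 of them changed), and 12869 genes passed the filter there. Among the changed genes that passed, the test recovered 52.1% of those changed 2-fold and 65.3% of those changed 4-fold. Of the 121 calls it made there, 5.79% were false. Counts were drawn independently between genes, so this share does not cover shifts that many genes have in common.

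Before the data were examined, gene lists were fixed for γδ T cell lineage and state, metabolism, sample handling, RNA quality and other cell types that the tissue or the sort gate could hold, and 27 lists had at least 5 tested genes. Each was tested with limma's camera (preset correlation 0.01, two-sided, adjusted over the 27 lists), which asks whether a list's genes moved more one way than the other genes. Camera with a correlation estimated for each list and fry, a directional test of the list alone, were alternatives. Fry also gives a mixed test, which asks whether members of a list changed in either direction. Adjustment can give lists with unlike unadjusted p the same adjusted p. The named genes were fixed by a rule set at the same time. It takes the 10 largest increases and the 10 largest decreases among genes with adjusted p under 0.05, a mean of at least 1 CPM, a symbol and no overlap between the diets (predicted genes and pseudogenes gave way). It adds up to 4 members of each list with the smallest p and a set of preset genes of interest, and genes outside the rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

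Alternatives fixed before the data were examined were RLE size factors, library size without composition factors, no count filter, a filter of 5 CPM in 4 samples, a block for the replicate number, a macrophage marker covariate, sample quality weights (voom), DESeq2, limma on log2 of the deposited FPKM plus 1 or 0.1, and leaving out each sample in turn. A stromal marker covariate, and leaving out KD replicates 3 and 4 together, with the preset or an estimated correlation, were added after seeing the data. Gene positions are those of GENCODE release M21 on GRCm38, matched by Ensembl identifier. Of the 72 genes located, 11 share exonic bases with another tested gene (Bcl2, Cd247, Cdc25b, Il12rb2, Junb, Kif20a, Oxct1, Pycard, Rps25, Tnfrsf18 and Trdc). Reads in shared bases cannot be assigned with certainty without strand, which leaves those levels less certain.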

Results

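The transcriptomes of γδ T cells sorted from visceral fat were compared between 4 samples from mice on chow and 4 samples from mice on a ketogenic diet for 1 week. The comparison addresses what these tissue T cells express while the animal relies on fat and ketone bodies for fuel. Chow libraries held 23940797, 26162952, 31926427 and 30918579 counts for replicates 1 to 4. KD libraries held 20843241, 26572315, 19796112 and 21710792. The similarity of samples within a diet overlapped that between diets. Pearson's r of log2 CPM across genes was 0.885 to 0.934 within a diet and 0.865 to 0.945 between diets. Trdc, which encodes the constant region of the δ receptor chain, stood at 4088 ± 95.2 CPM in chow and 4312 ± 319 CPM in KD (SD, n = 4 each).

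In γδ T cells of KD mice the genes that rose included S1pr1, Itgae, Ccr6 and Cpt1a, and those that fell included Lif, Myc, Btg2 and Socs3. S1pr1, the receptor that lets lymphocytes leave tissues along sphingosine-1-phosphate, rose from 134 ± 5.65 to 356 ± 57.6 CPM (log2 fold change 1.41, SE 0.11, adjusted p = 0.00157). Itgae, the αE integrin chain (CD103) that binds E-cadherin, rose from 13.3 ± 3.36 to 103 ± 31.2 CPM (log2 fold change 2.96, SE 0.27, adjusted p = 0.00198). Ccr6, the CCL20 receptor typical of IL-17-producing γδ T cells, rose by 1.73 (SE 0.24, adjusted p = 0.018) on the log2 scale. Cpt1a, the enzyme that commits long-chain fatty acids to mitochondrial oxidation, rose by 1.21 (SE 0.18, adjusted p = 0.0246). The transcripts of Lif, a cytokine of the IL-6 family (log2 fold change -1.22, SE 0.16, adjusted p = 0.0144), and Myc, a driver of growth (-0.86, SE 0.15, adjusted p = 0.0463), fell. So did those of Btg2, an antiproliferative early response gene (-0.57, SE 0.09, adjusted p = 0.0247), and Socs3, a feedback inhibitor of cytokine signalling (-0.64, SE 0.11, adjusted p = 0.041).

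**Figure D1:**
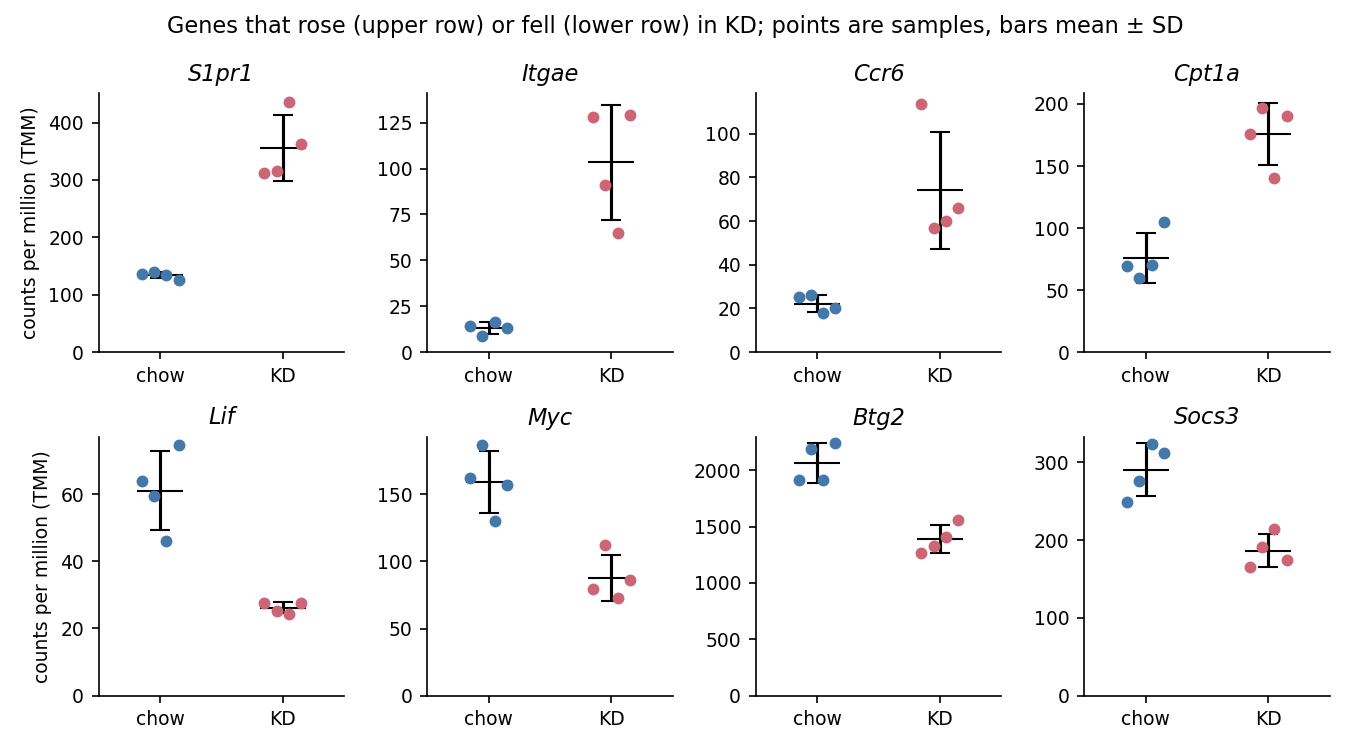
CPM (TMM-scaled, vertical axes from 0) of S1pr1, Itgae, Ccr6 and Cpt1a, which rose in KD, and of Lif, Myc, Btg2 and Socs3, which fell. Points are samples (blue, chow; red, KD) and bars the mean ± SD of 4; in each panel all KD samples lie on one side of all chow samples.

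Across the transcriptome 44 genes rose and 24 fell in KD among 13397 tested, and 1157 had an unadjusted p under 0.05. All 68 are protein coding, and in each of them the KD and chow samples did not overlap. Among all tested genes 810 (6.05%) were separated in this way, where chance gives 2.86%. The rise was at least 2-fold for 28 genes and the fall at least 2-fold for 4. Fits without chow replicates 1 to 4 in turn called 44, 34, 21 and 12 genes, with 32, 29, 19 and 12 of the 68 among them. Fits without KD replicates 1 to 4 called 21, 21, 20 and 22, with 20, 20, 19 and 22 of the 68 among them. Of the 68 genes, 11 were called in all 8 of these fits, S1pr1, Itgae and Tppp3 among them, and 21 in none. Ccr6 was called in 5, Lif in 4, Cpt1a and Btg2 in 2 and Myc and Socs3 in 1.

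**Figure D2:**
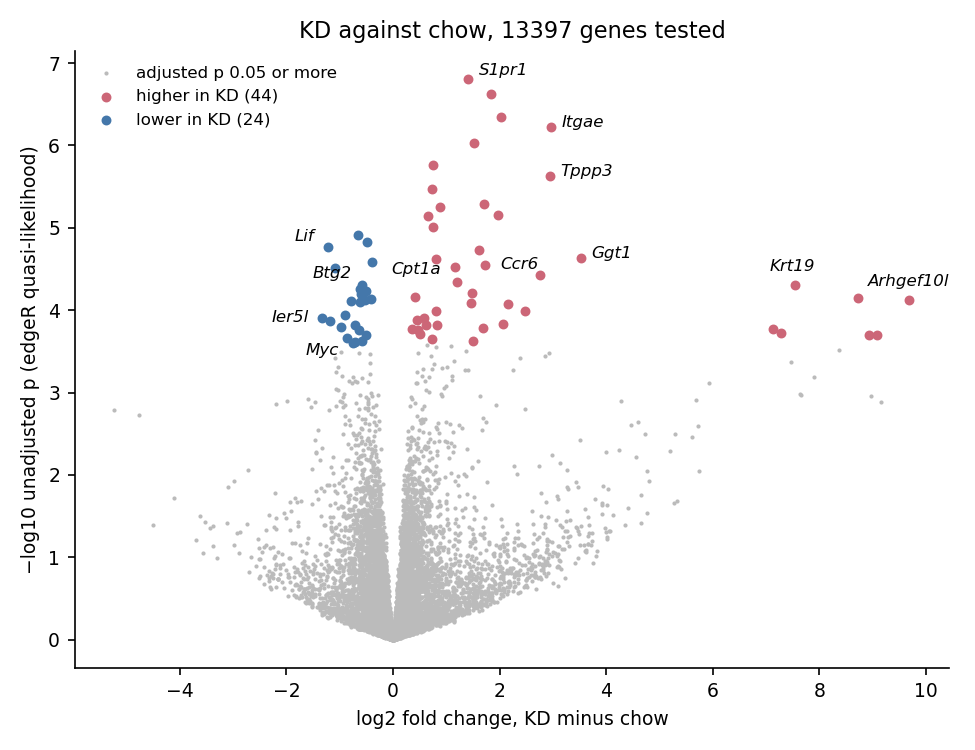
Log2 fold change (KD minus chow, horizontal) against −log10 of the unadjusted p (vertical) for the 13397 genes tested, each point a gene. The 44 genes higher in KD are red and the 24 lower in KD blue; the called genes with fitted changes above 7 are those with 0 to 3 counts over the 4 chow libraries.

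The 10 largest increases fall into genes nearly silent in chow and genes raised from a measurable level. Ggt1, a γ-glutamyltransferase of glutathione turnover, rose from 3.46 ± 2.26 to 39.9 ± 15.2 CPM (adjusted p = 0.0169). Tppp3, a tubulin-binding protein, rose from 22.02 ± 9.58 to 169 ± 37.0 CPM (adjusted p = 0.00444), and Spon2, a secreted matrix protein, from 6.46 ± 3.68 to 43.7 ± 5.94 CPM (adjusted p = 0.0208). Arhgef10l, Krt7 and Cyp2j9 had 0 counts in all chow libraries and were at least 156-fold, 98.7-fold and 91.9-fold higher in KD against a floor of 3 counts over the group. Cyp2j9 is uncertain because it belongs to a cluster of similar genes. Postn, a matrix protein of fibroblasts, had 2 chow counts and 854 KD counts (ratio 540, 95% counting interval 149 to 4467). Krt19, an epithelial and mesothelial keratin, had 3 and 545 counts (ratio 230, interval 78.2 to 1118), and Zc3h12c 1 and 184 counts (ratio 233, interval 41.3 to 9241).

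The 10 largest decreases were smaller. Ier5l went from 159 ± 25.7 to 63.1 ± 19.2 CPM (log2 fold change -1.34, SE 0.22, adjusted p = 0.0373), and Lif had the next largest fall. Flrt2 (-1.17, adjusted p = 0.0381), Rab27b, a GTPase of granule transport (-1.09, adjusted p = 0.018), and Neurl3 (-0.98, adjusted p = 0.041) fell. Cdkn1a, the p21 cell cycle inhibitor (-0.90, adjusted p = 0.0359), Gadd45b, a stress response gene (-0.79, adjusted p = 0.0278), Ramp3, a subunit of adrenomedullin and calcitonin-family receptors (-0.74, adjusted p = 0.0488), and Rrad (-0.71, adjusted p = 0.04) fell as well. Myc was the remaining gene.

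RNA typical of other cells of fat differed between libraries and was highest in KD samples. Of the 18 tested stromal and mesothelial markers, 17 had a positive fold change (median 2.50, and 4.13 without chow replicate 4) and 1, Krt19, rose, also when adjusted over the list alone. The list was higher in KD by camera (adjusted p = 3.32e-08), a call lost at adjusted p = 0.465 with an estimated correlation. Its mean log2 CPM was -0.59, -0.88, -0.10 and 2.71 in chow replicates 1 to 4 and 0.49, 4.26, 4.24 and 4.0 in KD replicates 1 to 4. All 12 tested endothelial markers had a positive fold change (median 2.49, 0 called over all genes or adjusted over the list alone). Without chow replicate 1 this median was 4.22, and without KD replicate 3 or 4 it was 2.04 or 1.63 and the list was not called. Their means were 4.05 and 4.62 in KD replicates 3 and 4 and at most 1.94 in the other libraries. Camera called this list higher (adjusted p = 0.00485, and adjusted p = 0.534 with an estimated correlation). Without KD replicates 3 and 4 its median was -1.81 (adjusted p = 0.228) and the fold change of Fabp4 -1.77 (adjusted p = 0.822). Sparc, a matrix protein, reached 189 and 335 CPM in KD replicates 3 and 4; its chow mean was 15.9 ± 15.5 CPM. Aqp1, a water channel of endothelium, reached 41.6 and 145 CPM there against 1.15 ± 1.89 CPM in chow. Fabp4, the fatty acid binding protein of adipocytes and capillaries, was at 216 and 386 CPM in the same libraries and at no more than 33.0 CPM in the other libraries. The adipocyte list (5 tested, median 1.02, camera adjusted p = 0.0979) did not pass, and its median was 3.35 without chow replicate 4, 0.617 without chow replicate 2 and 0.629 without KD replicate 4. Without KD replicate 2 camera with the preset correlation called it higher (median 1.24, adjusted p = 0.0207).

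**Figure D3:**
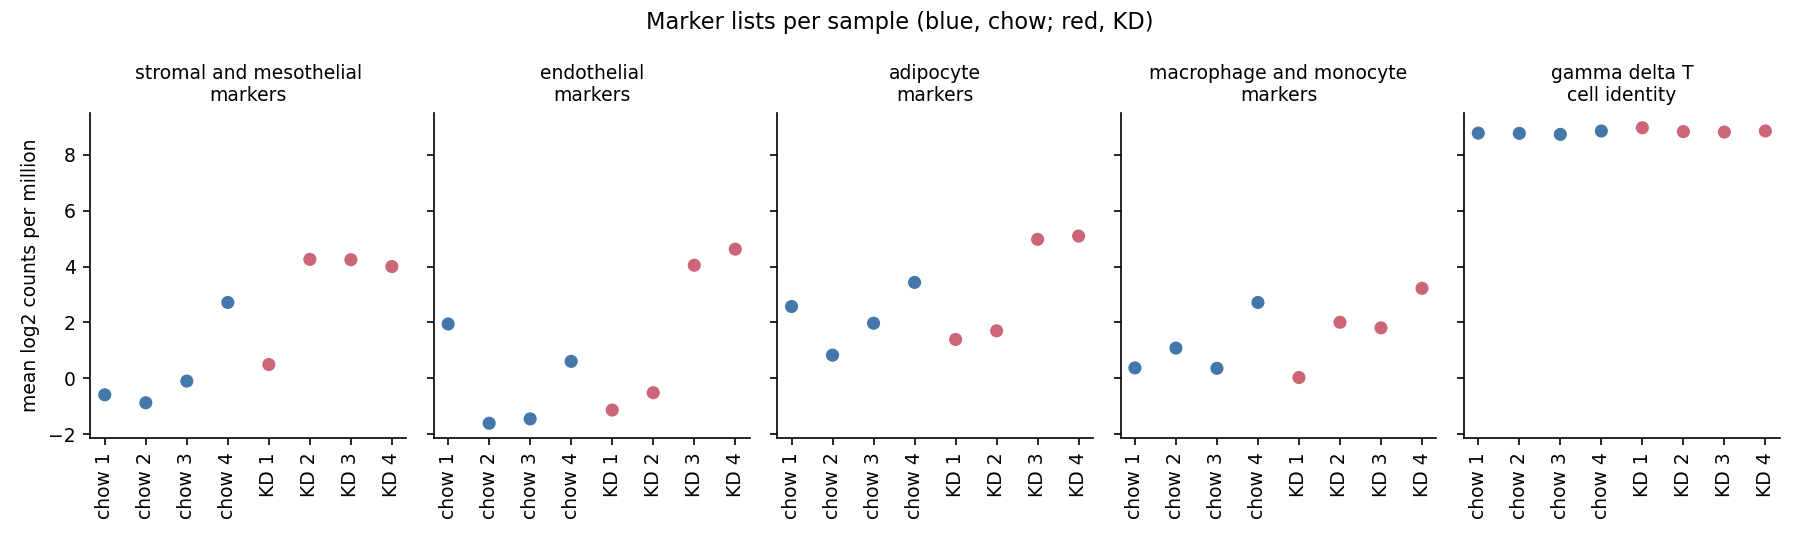
Mean log2 CPM (vertical) of the tested members of 5 lists in each sample (horizontal; blue, chow; red, KD). Stromal and mesothelial markers lie near 4 in KD replicates 2, 3 and 4, endothelial markers above 4 in KD replicates 3 and 4, and γδ T cell identity genes between 8.73 and 8.97 in all samples.

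Among the other cell type lists, NK cell and ILC2 markers (10 tested, 0 called, 1 lower adjusted over the list alone, median -0.19, and -0.091 without chow replicate 2) were lower in KD by camera (adjusted p = 0.0475, and adjusted p = 0.465 with an estimated correlation). Calca, a neuropeptide gene expressed by ILC2, was at 8.63 ± 1.54 CPM in chow and 3.14 ± 0.37 CPM in KD (adjusted p = 0.122). Macrophage and monocyte markers (camera adjusted p = 0.758), B cell markers (0.917), αβ T cell markers (0.559) and neutrophil, mast cell and erythroid markers (0.0828) did not pass, but the last of these were higher with the preset correlation without chow replicate 3 (median 1.51, adjusted p = 0.00545) or KD replicate 2 (0.808, adjusted p = 0.0393). Cd79b, a subunit of the B cell receptor, was the only B cell marker past the threshold adjusted over the list alone (31.97 ± 10.6 and 69.1 ± 11.7 CPM, adjusted p = 0.0847 over all genes).

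The identity genes of γδ T cells moved little, whereas members of the IL-17 program moved in both directions. Of the 20 identity genes 15 had a positive fold change (median 0.09, and 0.057 without chow replicate 3), and 0 passed over all genes or adjusted over the list alone. The smallest p belonged to the kinase gene Blk (log2 fold change 0.27, SE 0.08, adjusted p = 0.245), followed by the CD3ζ gene Cd247 (0.25, SE 0.08, adjusted p = 0.319). The list was higher by camera (adjusted p = 0.0396, and adjusted p = 0.465 with an estimated correlation). Of the 30 genes of the IL-17 program, 1 rose (Ccr6), 1 fell (Lmo4, a transcriptional cofactor: log2 fold change -0.71, SE 0.13, adjusted p = 0.0485) and 28 did not pass. Adjusted over the list alone, 7 rose and 3 fell. That list did not pass (adjusted p = 0.258), with a negative median (-0.02, and -0.030 to 0.039 without single samples) and a positive mean (0.11) and test direction. Il17a was at 57.8 ± 10.8 CPM in chow and 105 ± 34.3 CPM in KD (log2 fold change 0.86, SE 0.23, adjusted p = 0.216). The glycerol channel gene Aqp3 was at 277 ± 43.2 and 402 ± 24.0 CPM (adjusted p = 0.0847).

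The interferon-γ and cytotoxic program was lower in KD by camera (adjusted p = 0.000728, median -0.21, and -0.13 without chow replicate 4), although 0 of its 27 tested genes passed over all genes. Adjusted over the list alone 6 fell and 1 rose, and the list's adjusted p = 0.465 with an estimated correlation. Tbx21, which encodes T-bet, was at 363 ± 71.1 CPM in chow and 248 ± 41.1 CPM in KD (log2 fold change -0.55, SE 0.16, adjusted p = 0.264). Ifng (-0.56, adjusted p = 0.544), the Fas ligand gene Fasl (-0.47, adjusted p = 0.239) and Il12rb2, an IL-12 receptor chain whose exons overlap those of Serbp1 on the other strand (-1.21, adjusted p = 0.131), had negative fold changes. Klrk1, which encodes the receptor NKG2D, had a positive value (0.40, adjusted p = 0.216).

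Camera placed 4 lists of activation, stress and cytokine genes lower in KD, with few members called and none of the calls kept with an estimated correlation. In the immediate early and heat shock list 2 of 26 genes fell (Btg2 and Socs3; 3 adjusted over the list alone) and 11 had a positive fold change (median -0.089, and 0.0050 with the call lost without chow replicate 4). Its mean log2 CPM was 7.65, 7.88, 8.21 and 8.34 in KD replicates 1 to 4 and 8.07 to 8.44 in chow, and Junb had a log2 fold change of -0.51 (SE 0.11, adjusted p = 0.114). In the activation and checkpoint list 1 of 24 fell (Myc); adjusted over the list alone 3 fell and 1 rose. Its median (-0.13, and -0.20 without KD replicate 4) and its test were negative and its mean (0.15) positive. Havcr2, which encodes the checkpoint receptor TIM-3, was at 1.94 ± 1.85 CPM in chow and 21.9 ± 5.21 CPM in KD (adjusted p = 0.214). Tnfrsf18, which encodes GITR, was at 149 ± 11.1 and 110 ± 3.47 CPM (adjusted p = 0.0694). In the tissue repair and regulatory cytokine list 1 of 22 fell (Lif; 2 adjusted over the list alone), with Tnfsf11, which encodes RANKL, at 652 ± 138 and 400 ± 48.9 CPM (adjusted p = 0.0904). The NF-κB and inflammasome list had 0 of 20 called and 1 higher adjusted over the list alone (Pycard, the inflammasome adaptor gene: 0.59, adjusted p = 0.0904), with Tnf at -0.61 (adjusted p = 0.288). Camera gave the 4 lists, in this order, adjusted p = 0.0034, 0.0139, 0.0427 and 0.0326, and each has an adjusted p = 0.465 with an estimated correlation. That value is shared through the adjustment. Camera's unadjusted p with an estimated correlation was 0.218, 0.211, 0.153 and 0.0938. The type I interferon list (31 tested, adjusted p = 0.917) did not pass.

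The quiescence and recirculation list was higher in KD by camera (adjusted p = 0.000728, and adjusted p = 0.465 with an estimated correlation). Of its 22 genes, 1 rose (S1pr1); adjusted over the list alone 2 rose and 1 fell. Klf2, the factor that drives S1pr1 transcription, was at 212 ± 62.5 and 399 ± 83.7 CPM (adjusted p = 0.112), and the survival gene Bcl2 at 510 ± 20.8 and 367 ± 59.2 CPM (adjusted p = 0.124). The tissue residency list did not pass (18 tested, adjusted p = 0.64): Itgae rose, and Bhlhe40, a transcription factor of resident T cells, had a log2 fold change of -0.52 (adjusted p = 0.166). All 40 cell cycle genes were tested and 0 passed, with 1 higher adjusted over the list alone. Of them 36 had a positive fold change (median 0.25, and 0.16 without KD replicate 4), and the list was higher by camera (adjusted p = 0.000117, and adjusted p = 0.465 with an estimated correlation). Mcm6, a subunit of the replicative helicase, was at 164 ± 10.9 and 226 ± 23.9 CPM (adjusted p = 0.0907), Kif20a, a mitotic kinesin, at 13.8 ± 2.69 and 24.4 ± 5.95 CPM (adjusted p = 0.265), and Mki67 at 32.8 ± 11.2 and 35.6 ± 8.37 CPM (adjusted p = 0.961). The list's mean log2 CPM was highest in KD replicates 3 and 4 (5.55 and 5.61), the libraries with the most endothelial marker RNA, and 5.06 to 5.36 in the other libraries.

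Of 36 genes for fatty acid uptake and oxidation 1 rose (Cpt1a) and 35 did not pass; adjusted over the list alone 3 rose. Slc25a20, the mitochondrial acylcarnitine carrier (63.4 ± 12.5 and 94.2 ± 3.34 CPM, adjusted p = 0.188), and Plin2, a lipid droplet coat protein (216 ± 62.5 and 344 ± 17.8 CPM, adjusted p = 0.192), had positive fold changes. Acsl1, an acyl-CoA synthetase, had a negative value (-1.01, adjusted p = 0.378). The list was higher in KD by camera (adjusted p = 0.0427, and adjusted p = 0.465 with an estimated correlation), with its highest means in KD replicates 3 and 4 (5.86 and 5.99, and 5.34 to 5.63 elsewhere). Glycolysis genes (25 tested, 0 called, 1 lower adjusted over the list alone, median -0.06) and genes of cholesterol and fatty acid synthesis (31 tested, 0 called over all genes or adjusted over the list alone, median -0.27) were lower (adjusted p = 0.0396 and 0.0034). Each of these lists has an adjusted p = 0.465 with an estimated correlation. Without single samples the glycolysis median ran from -0.11 (chow replicate 2) to -0.022 (chow replicate 1), and the synthesis median was -0.068 without chow replicate 3 and -0.14 without KD replicate 1, both times with the call lost. Hk2, the inducible hexokinase, was at 44.4 ± 6.76 and 23.0 ± 5.03 CPM (adjusted p = 0.0847), and Insig1, a brake on sterol synthesis, at 51.5 ± 12.3 and 27.6 ± 11.4 CPM (adjusted p = 0.404).

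Ketone body metabolism did not pass as a list (9 tested, adjusted p = 0.612, median 0.08 and mean -0.03). Bdh1 and Oxct1, which act in ketone body oxidation, had log2 fold changes of -0.55 (SE 0.28, adjusted p = 0.638) and -0.12 (SE 0.18, adjusted p = 0.937). Of the other preset genes, Areg, a repair cytokine (log2 fold change 0.69, SE 0.40, adjusted p = 0.705), and Tgfb1 (-0.10, SE 0.15, adjusted p = 0.925) did not pass. Pdk4 had 2 counts in chow and 38 in KD, Il10 had 0 and 12, and Nlrp3 had 1 and 12. These 3 genes missed the count filter and did not pass without it (adjusted p = 0.512, 0.494 and 0.554). Hcar2, the receptor for β-hydroxybutyrate, had 0 counts in all 8 libraries, so that a change in it was not detectable at this depth.

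Nuclear genes of oxidative phosphorylation (75 tested, adjusted p = 0.596), the integrated stress response (17 tested, adjusted p = 0.899) and mitochondrially encoded genes (13 tested, adjusted p = 0.692) did not pass. Without KD replicate 2 the mitochondrially encoded genes were higher with the preset correlation (median 0.21, adjusted p = 0.0214), but without KD replicates 3 and 4 the mitochondrially encoded genes were lower (median -0.19, adjusted p = 0.000186), a call lost at adjusted p = 0.584 with an estimated correlation. Cytosolic ribosomal protein genes were lower by camera (83 tested, 74 with a negative fold change, median -0.13, adjusted p = 1.06e-06), with 0 called over all genes or adjusted over the list alone and an adjusted p = 0.534 with an estimated correlation. Their mean log2 CPM was 7.05 in KD replicate 2 and 7.31 to 7.54 in the other libraries, and without that replicate the call was lost, with a median of -0.042. Rps25, uncertain because of its pseudogene copies, was at 346 ± 38.0 and 257 ± 37.0 CPM (adjusted p = 0.227).

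**Figure D4:**
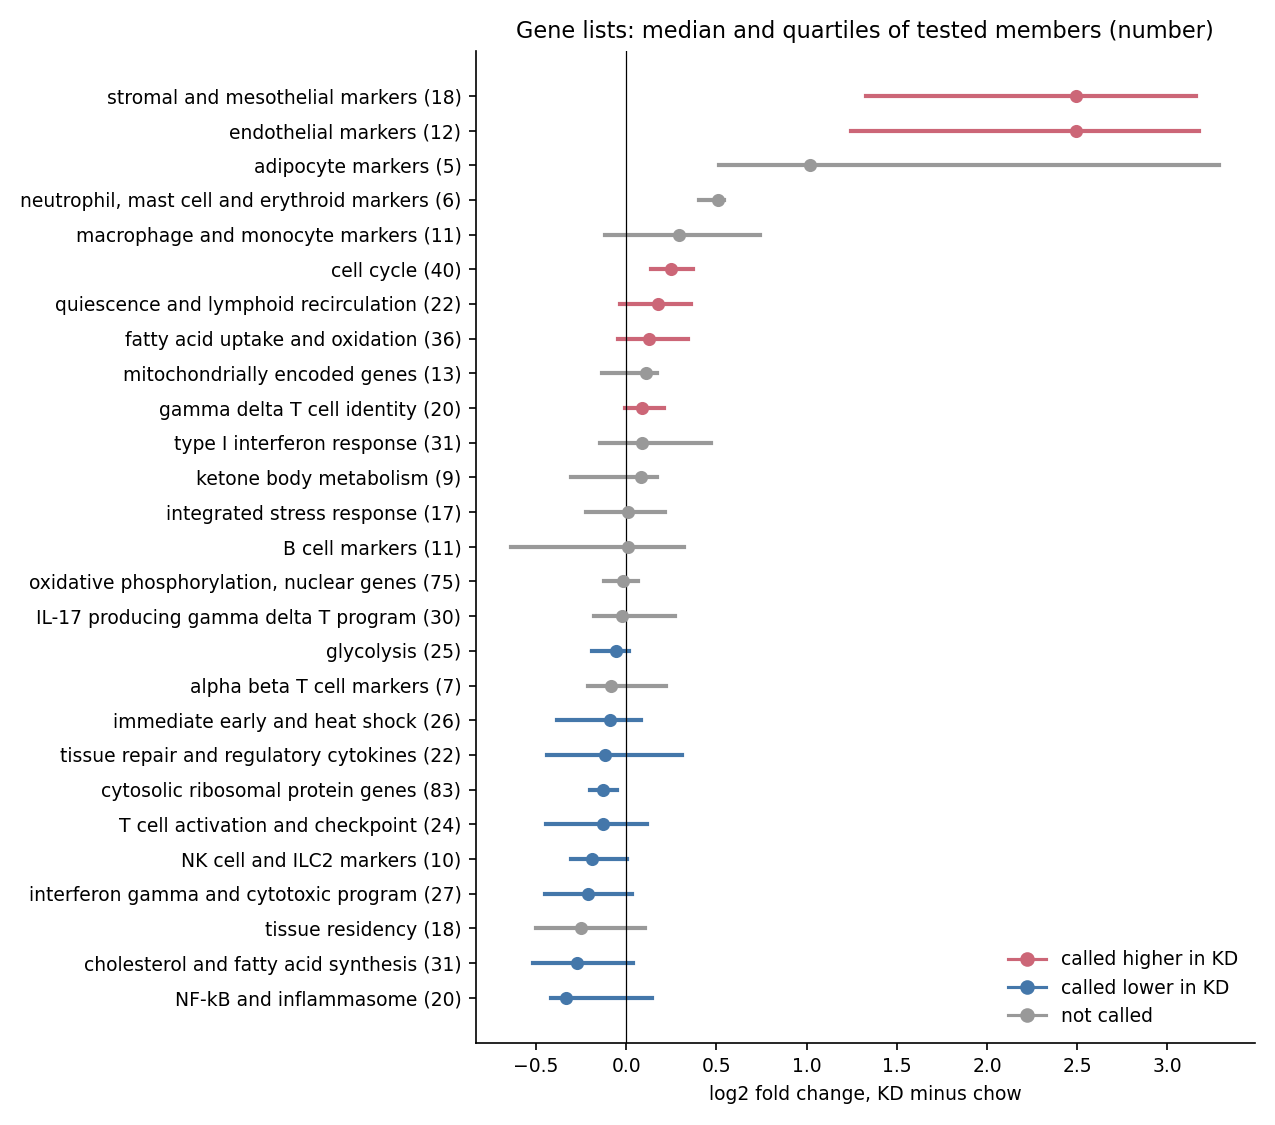
Median (points) and quartiles (lines) of the log2 fold changes, KD minus chow, of the tested members of the 27 lists, with the number of members in parentheses. Camera with a preset correlation called 6 lists higher (red) and 9 lower (blue) in KD; 12 were not called (grey), and with estimated correlations 0 were.

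Of the 27 lists, 6 were higher and 9 lower in KD by camera with the preset correlation. With correlations estimated from the data 0 passed (1, quiescence and recirculation, had an unadjusted p under 0.05). By fry's directional test 0 passed as well (4 had an unadjusted p under 0.05). Fry's mixed test called 15 lists, which says nothing of a shared direction. Among them were IL-17 program (adjusted p = 1.08e-06), tissue residency (3.19e-05), integrated stress response (7.08e-05) and type I interferon (0.00493) genes, not called by camera. Cell cycle, cholesterol and fatty acid synthesis, endothelial and ribosomal protein genes were not among them. Of the 15 lists that camera called, the interferon-γ program, cell cycle, quiescence and stromal markers passed in all 8 fits without a single sample. Ribosomal proteins were called in 7 of these fits, which used the preset correlation alone. Cholesterol and fatty acid synthesis and endothelial markers were called in 6 of them, activation, immediate early and NF-κB genes in 5, γδ T cell identity, tissue repair, fatty acid oxidation and glycolysis genes in 3, and NK cell and ILC2 markers in 2. Leaving out chow replicate 4 or KD replicate 1 left 3 lists lower, leaving out KD replicate 2 left 5 lower, and leaving out KD replicate 4 left 3 higher. DESeq2 called 470 genes where edgeR called 68, all 68 among them. With the stromal marker mean as a covariate 12 genes were called, 10 of them among the 68. Without KD replicates 3 and 4 there were 4 (S1pr1, Itgae and, named after their values were seen, Acsbg1 and Rom1). The stromal covariate and this omission were chosen after seeing the data.

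On GRCm38, S1pr1 (ENSMUSG00000045092.8) spans chromosome 3 from 115710433 to 115715072, Itgae (ENSMUSG00000005947.11) chromosome 11 from 73090583 to 73147446, Ccr6 (ENSMUSG00000040899.13) chromosome 17 from 8236043 to 8257141 and Cpt1a (ENSMUSG00000024900.4) chromosome 19 from 3322334 to 3385733. Lif (ENSMUSG00000034394.14) spans chromosome 11 from 4257557 to 4272514, Myc (ENSMUSG00000022346.14) chromosome 15 from 61985391 to 61990374, Btg2 (ENSMUSG00000020423.6) chromosome 1 from 134075170 to 134079120 and Socs3 (ENSMUSG00000053113.3) chromosome 11 from 117966079 to 117970047. None of these 8 genes shares exonic bases with another tested gene.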

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

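The tests of other-cell RNA and of dilution, and those with a covariate or a left-out library, were chosen after the results were seen, whereas the correlation with the immediate early genes and the counts over other splits of the samples were set before their results were known. Of 149 groups of 4 values examined, 9 held a sample far from the others, against about 1 in 20 that chance gives. KD replicate 1 was low in stromal and mesothelial marker RNA, with a mean log2 CPM of 0.49 where the other KD samples had 4.0 to 4.26 (gap over range 0.932). It was high in Ccr6 (114 CPM against 66.0 or less, 0.838), Ifng (31.98 against 23.0 or less, 0.957) and Lgals3 (177 against 103 or less, 0.957). KD replicate 3 was low in Havcr2 (14.2 against 23.4 or more, 0.848). Chow replicate 2 was low in Cd247 (543 CPM against 624 or more, 0.865) and held the single Zc3h12c count of the chow libraries (gap over range 1). Chow replicate 4 was high in Il12rb2 (20.004 against 14.2 or less, 0.899) and Aqp1 (3.97 against 0.316 or less, 0.930).

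Stromal, mesothelial and endothelial RNA was higher in KD samples 2, 3 and 4 or 3 and 4, and a sort for γδ T cells would leave such cells out. Expression in the sorted cells raised by the diet in each KD sample is argued against for the endothelial markers. Their means in KD replicates 1 and 2 (-1.14 and -0.52) lay within the chow range. Of the 30 tested markers, 3 (0 of 12 endothelial, 3 of 18 stromal and mesothelial) had every KD sample above every chow sample. Among all tested genes 6.05% were separated in either direction. For the stromal list this does not decide, since chow replicate 4 alone (mean 2.71) stood above KD replicate 1 (0.49). Carry-over that varied from sample to sample is a candidate explanation: markers of the same list rose and fell together among samples of a diet (median correlation 0.689, quartiles 0.389 and 0.831), and Sparc, one of the abundant markers, ranged from 4.24 to 335 CPM among the KD samples. Of these markers 6 were at 1 CPM or more in all chow libraries and none stands in another list. Whether the diet changed how much of the tissue came through the sort stays open and was not tested.

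The same carry-over may account for genes that rose from almost nothing. For the rest it was argued against in KD replicate 1, and only for the genes called without that library. Among the 37 genes that rose from a chow mean of 0.5 CPM or more, the median correlation with the stromal marker mean within diets was -0.199 (quartiles -0.533 and 0.114), at a within-diet SD (median 0.209, log2) near that of other genes at their level (0.227). A gene that follows the markers varies within a diet and is hard to call. The choice of called genes thus in part set this correlation and the covariate result below, and neither decides alone. A fit without KD replicate 1, whose marker mean lay within the chow range, called 16 genes higher from that chow level, and in the left-out library these showed a median of 1.04 times the log2 fold change of the other KD samples (quartiles 0.924 and 1.18). With the marker mean as a covariate the median log2 fold change of the 37 went from 1.41 to 1.34 and 10 stayed called; for the other 27 the standard error grew by a median factor of 1.41, while the log2 fold changes came to 0.802 to 1.35 times their size and were smaller for 12. The 7 genes that rose from under 0.5 CPM were Arhgef10l, Krt7, Cyp2j9, Postn, Krt19, Zc3h12c and Hsbp1l1, the last below the mean for naming. Their median correlation was 0.019 with quartiles of -0.113 and 0.540. In KD replicate 1, low in the markers, Postn, Krt19 and Krt7 (0.524, 1.33 and 1.29 CPM) lay below the other KD samples. Arhgef10l, Zc3h12c and Cyp2j9 (3.96, 2.19 and 2.05 CPM) lay among them and Hsbp1l1 (3.34 CPM) above. With the covariate the median log2 fold change of the 7 went from 8.72 to 7.71, all 7 kept their sign and 0 stayed called. Carry-over and expression in the sorted cells cannot be told apart with 7 genes.

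For the 24 genes that fell, less handling stress in the KD samples stays open. Within diets their median correlation with the other immediate early and heat shock genes was 0.192 (quartiles -0.093 and 0.397). With the mean of the uncalled ones as a covariate the median log2 fold change went from -0.649 to -0.646 and 8 stayed called (median factor on the standard error 1.09). That mean leaves out Btg2 and Socs3, the members that fell. It can miss part of a handling difference between the diets, so the unchanged fold does not decide. Fits without KD replicate 3 or 4, whose mean of the uncalled ones lay within the chow range, called 2 and 6 genes lower. In the left-out library these showed a median of 0.661 and 0.886 times the log2 fold change of the other KD samples. These are too few genes to decide. The immediate early and heat shock list was itself lower in KD by camera (adjusted p = 0.0034, and adjusted p = 0.465 with an estimated correlation). This goes with less handling stress, but the list holds Btg2 and Socs3, which are among the 24 genes. The list was not tested without them. Its call was lost without chow replicate 4, KD replicate 1 or KD replicate 2. Dilution of γδ T cell RNA by that of other cells was argued against, since the γδ T cell identity genes had a median log2 fold change of 0.088 (quartiles -0.005 and 0.210). A response of the cells to the diet stays open as well, as an untested hypothesis.

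Chance was argued against, but not excluded, as the source of the gene count. Among the 35 splits of the 8 samples into 4 and 4, 1, the real one, called as many as 68 genes. The highest of the others called 2. With 35 splits the test cannot give less than 1 of 35, and the other splits mix the diets, which can lower their counts. For lists the real split was also the only one of 35 to call 15, but others called up to 12 with the preset correlation, so that list counts near that size arose without a split by diet.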

How the results depend on the processing

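The stromal marker covariate and the omission of KD replicates 3 and 4 were chosen after seeing the data. All 68 called genes kept their sign wherever they were tested (61 with the 5 CPM filter, 68 elsewhere). The numbers of genes higher and lower in KD (44 and 24) stayed within 1.5 times with RLE factors, library size alone, no filter and voom weights. The 5 CPM filter gave 45 lower on fewer tested genes. DESeq2 gave 298 and 172, and FPKM with limma 82 and 44 (pseudocount 1) or 79 and 40 (0.1). The macrophage covariate gave 8 lower and the stromal covariate 11 and 1. With the stromal covariate 0 of the 24 genes that fell stayed called. Their median log2 fold change was -0.702 with it, and the standard error grew by a median factor of 1.38. Without KD replicates 3 and 4 there were 4 and 0, and without single samples 12 to 32 and 0 to 13, with fewer samples in each fit. The cause of the other shifts was not tested.

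No pairing by replicate number was seen: deviations of same-numbered samples correlated at -0.114 to 0.054 across genes, and 0 of 8 samples correlated best with their own number. With 4 samples per diet this cannot exclude a shared day or litter. With the replicate block 11 genes were higher and 1 lower, which says nothing about the size of the effects.

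Lists higher and lower in KD (6 and 9) were 0 and 0 with estimated correlations and 0 and 0 by fry, 3 to 8 and 3 to 7 without single samples, 2 higher with the stromal covariate, 3 higher without KD replicates 3 and 4, and 0 and 0 without them and with estimated correlations.

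For single genes, 1091 of the comparisons between a named gene and an alternative kept direction and side of the threshold, 275 lost and 59 gained a call, and 8 turned. For lists 367 kept both, 111 lost and 7 gained a call, and 52 turned, most of them in lists that did not pass; values below are log2 fold changes or list medians, with the turn read from the test. Without single samples Mki67 ran from -0.084 to 0.29, Oxct1 from -0.24 to 0.0095 and Tgfb1 from -0.18 to 0.047. List medians ran from -0.39 to 0.30 (B cell), -0.0081 to 0.13 (ketone body), -0.35 to 0.90 (macrophage), -0.015 to 0.21 (mitochondrially encoded), -0.053 to 0.029 (oxidative phosphorylation), -0.35 to -0.077 (residency) and -0.060 to 0.16 (type I interferon). Without the filter the turned lists were ketone body (0.14), type I interferon (0.075) and B cell (-0.26), and with the 5 CPM filter type I interferon (0.0027). With the macrophage covariate they were oxidative phosphorylation (0.0016), type I interferon (0.034), macrophage (-0.42) and B cell (-0.23), and with voom weights type I interferon (0.047) and B cell (-0.32). The stromal covariate turned Sparc (-0.30) and Tgfb1 (0.059) and the lists for oxidative phosphorylation (0.036), integrated stress (-0.10), type I interferon (-0.074), macrophage (-0.92), B cell (-0.43), adipocyte (0.074), stromal (-0.76, a list adjusted for itself) and ribosomal proteins (0.0011). Without KD replicates 3 and 4, Fabp4 (-1.77) and Areg (-0.15) turned, as did integrated stress (-0.054), type I interferon (-0.20), macrophage (-0.32), B cell (-0.26), adipocyte (-0.97), endothelial (-1.81) and mitochondrially encoded genes (-0.19), these lists with either correlation. The cause of these turns was not tested.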

Other observations

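Other called genes belong to no list above, and those in this paragraph were chosen after their values were seen. Acsbg1, an acyl-CoA synthetase of long-chain fatty acids, rose from 77.1 ± 9.39 to 277 ± 56.2 CPM (SD, n = 4 each; log2 fold change 1.85, SE 0.15, edgeR adjusted p = 0.00157), higher in 4 of 4 KD samples than in any chow sample, as holds for each gene that rose here. Nrp1, which encodes neuropilin-1 (log2 fold change 0.89, adjusted p = 0.00747), rose too, as did Itgb1, the β1 integrin chain (0.81, adjusted p = 0.0169), Lgals3, which encodes galectin-3 (1.97, adjusted p = 0.00799), and Cd48, a ligand of the receptor 2B4 (0.76, adjusted p = 0.00999). Cdc25b, a phosphatase of mitotic entry whose exons overlap those of Spef1, rose by 1.52 (adjusted p = 0.00252). The transcripts of Csrnp1, an early response factor (-0.66, adjusted p = 0.0118), and Ppp1r15a, a stress-induced phosphatase subunit known as GADD34 (-0.49, adjusted p = 0.0133), fell.

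Shares of receptor V genes differed between the diets by less than the spread between samples. Tcrg-V6 made up 68.4 ± 3.68% of counts over γ chain V genes in chow and 66.6 ± 3.77% in KD (SD, n = 4 each; two-sided exact permutation p = 0.514). Trdv4 made up 93.6 ± 0.91% and 93.5 ± 2.08% of counts over δ chain V genes (two-sided exact permutation p = 0.971).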
